A study of Saccharomyces cerevisiae BY4741 with 25 samples.

How the data were processed

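Genomic DNA of 9 yeast libraries was analysed, 1 of both parental strains together (YTT66 and YTT67) and 1 for each of the mutants RRC1 to RRC8. The series holds 25 samples, and the 16 chromatin immunoprecipitation samples of Uaf30 and their controls were not analysed here, since no files for them were among those used. Per the labels' protocols, clones of a mutant were grown separately and harvested together before the DNA was extracted, so each mutant is 1 library. Strain names in the labels put RRC1 and RRC4 under YTT67 and the other 6 mutants under YTT66. Median depth over all calls was 37 reads in the parental pool and 47, 51, 25.5, 51, 39, 19, 40 and 39 reads in RRC1 to RRC8. The number of clones per pool, the backcross generations and the mutagen are not given in the sources used here.

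The deposited data were 17 lists of called variants, a list of all variants for each library and a second, shortened list for each mutant. Each row gives a gene or region, chromosome, position, reference and alternate allele, and the predicted effect on the protein. Per the file headers, each call carries a score (named MapQ there), the number of reads covering the position (a read count) and the percent of reads with the alternate allele. Bowtie 1.0.0, SAMtools 0.1.19 and MACS2 are named in the submitters' processing notes of part of the samples, with no role for any of them. The variant caller, its filters and the genome build are not given in the sources used here. Positions are those of the authors' files. Of 451 loci with a protein-changing call, 422 were in the RefSeq gene table of assembly R64, and all 1511 protein-changing effects in them lay inside the locus of that assembly. No coordinates were taken from that table, which served for names and neighbours only.

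The deposited percent is rounded down. At all 3148 calls with up to 60 reads the value equals a whole number of reads over the depth, rounded down, while rounding to the nearest percent would have failed at some of them (2445 matched). The alternate read number was therefore recovered as the fewest reads that give the printed percent, which is exact up to 100 reads and a lower bound above that. The shortened lists are subsets of the full ones. All 984 calls missing from the 8 shortened lists were also parental calls, but 1324 of the 3028 calls they kept were parental calls too, so the full lists were used and the shortened ones served as an alternative.

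A call was pool-specific when its position and alleles were absent from the parental list, with at least 10 reads. It was near-fixed when its share was at least 90% and a two-sided exact binomial test against 0.5 gave a Benjamini-Hochberg adjusted p under 0.05 over the pool-specific calls of that pool. Protein-changing calls were missense, stop gain or loss, frameshift and in-frame insertion or deletion, from the deposited annotation. Shares carry exact (Clopper-Pearson) 95% intervals. Reads from amplified libraries are not independent molecules, so intervals cover counting error only, and neither tests nor intervals cover which clones entered a pool. G:C to A:T shares of pool-specific and parental-shared single-base calls were compared within each pool by a two-sided Fisher's exact test, adjusted over 8 pools. Shares within 50 kb of the change in the named gene, that change left out, were compared with all others by a two-sided permutation test of the mean, exact where under 10 calls were near. Each exact permutation p counted every choice of calls.

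The named genes follow a rule fixed beforehand: the title genes, up to 10 genes per pool with near-fixed protein-changing calls by share and then depth, any gene of the 7 fixed lists with a protein-changing pool-specific call, and any gene with such calls in at least 2 mutant pools at different positions. The rule gave 56 genes. Genes named for calls downstream of them or for their place beside a near-fixed change, and CTR9, SIR2, NET1, FOB1, LEU2 and COX1, were chosen after their values were seen. The tests, thresholds, gene lists and most alternatives were fixed before the data were examined. The restriction to calls with a score of at least 200, no parental call of any allele at the position and at most 1 other list with a call there was added afterwards, since many calls of repeats carry several alleles and escape an exact match.

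Alternatives covered absence from the other 7 mutant lists, no minimum depth or 20 reads, single-base calls only, the shortened lists, shares of at least 80% or 95%, the share without a test, windows of 25 and 100 kb, matches within 5 bases and narrower sets for the G:C to A:T share. The effective number of clones in a pool was estimated from the variance of shares beyond read counting, over high-score G:C to A:T calls on chromosomes without a near-fixed change, with 10000 bootstrap draws. The high score removes calls of low share and so narrows the spread, which raises this estimate. Scripts ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

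The steps were tested on simulated data. At the real depths of the pool-specific calls of each pool, 20 rounds with every 10th site at a share of 98% and the others at 50% gave recovery of 98.5% of the near-fixed sites over the 8 pools, from 95.6% in RRC6 to 100% in RRC1. Of 24200 simulated sites at 50%, 1 was called near-fixed. The exact permutation count matched a full listing in 30 of 30 trials. With 40 simulated clones the median estimate of the clone number was 41.0, and with 10 it was 9.74. No score filter was applied to these simulated shares, so the bias from that filter was not measured. Fisher's test called 5.5% of 200 simulated pools without a difference.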

Results

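Whole-genome sequencing was used to locate the mutations behind 8 budding yeast mutants, RRC1 to RRC8, in the BY4741 background. The series' design text states that the mutants were sought for loss of repression of SIR2, the histone deacetylase gene whose product holds the ribosomal RNA gene repeats stable. Clones with the mutant phenotype, grown from spores of a backcross, were combined and sequenced as 1 library per mutant. A 9th library combined both starting strains, YTT66 and YTT67. In such a pool an allele that gives the phenotype should be carried by nearly all reads, and an unlinked change by about 50% of them. The lists of called variants held 447 calls in the parental pool and 449 to 598 in the mutant pools. The median depth at calls with a score of 200 or more was 44 reads in RRC6 and 58.5 to 70 reads in the other 8 libraries. There were no replicate libraries, so every test compares reads or calls within a library. Reads from amplified libraries without molecular identifiers are not independent molecules, and the intervals cover counting error only. The titles name a gene for 4 of the mutant pools (RRC1, RRC2, RRC3 and RRC5). The description of RRC4 speaks of the parental strains while its title and strain name give a mutant, and it was treated as a mutant pool.

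In each of the 4 pools whose title names a gene, that gene carried a protein-changing call on all reads. All 4 genes encode subunits of the upstream activating factor (UAF), the complex that recruits the RNA polymerase I machinery to the ribosomal RNA gene promoter. RRC1 carried R309Q in RRN9 (YMR270C, chromosome 13, position 805498), with 77 of 77 reads alternate (100%, exact Clopper-Pearson 95% interval 95.3 to 100%). RRC2 carried the stop change Q117* in RRN10 (YBL025W, chromosome 2, position 171829) on 50 of 50 reads (92.9 to 100%). RRC3 carried S78N in RRN5 (YLR141W, chromosome 12, position 423915) on 34 of 34 reads (89.7 to 100%). RRC5 carried a frameshift at G112 in UAF30 (YOR295W, chromosome 15, position 869540), read as AGGG to AGG, on 45 of 45 reads (92.1 to 100%). Against a share of 50%, the two-sided exact binomial test gave Benjamini-Hochberg adjusted p = 1.00e-21 for RRN9, 5.79e-14 for RRN10, 2.06e-09 for RRN5 and 1.04e-12 for UAF30. The parental list held 0 calls in any of the 4 genes, but it gives no depth at positions without a call, so the parental and mutant reads were not compared by a test. Calls in RRN9, RRN10 and RRN5 were in no other mutant list, whereas the UAF30 frameshift was in 1 other list.

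That other list was RRC8, and near-fixed protein changes were also found in the 3 remaining pools without a gene in the title. RRC8 carried the same UAF30 frameshift on 98% of 55 reads (exact 95% interval 90.3 to 100%). RRC4 carried the stop change W1404* in CHD1 (YER164W, chromosome 5, position 509603), which encodes a chromatin remodelling ATPase, on 98% of 59 reads (90.9 to 100%). RRC6 carried a frameshift at E363 in IES1 (YFL013C, chromosome 6, position 108843), a subunit gene of the INO80 chromatin remodelling complex, on 100% of 44 reads (92.0 to 100%). RRC7 carried a pair of missense changes on different chromosomes. These were E751K in UBP3 (YER151C, chromosome 5, position 470174), which encodes a ubiquitin protease, on 100% of 72 reads (95.01 to 100%), and C225Y in YNG2 (YHR090C, chromosome 8, position 283952), a subunit gene of the NuA4 histone acetyltransferase, on 98% of 63 reads (91.5 to 100%). The adjusted p of the exact binomial test was 1.45e-14 for CHD1, 5.80e-12 for IES1, 6.40e-20 for UBP3, 4.19e-16 for YNG2 and 7.40e-14 for UAF30 in RRC8.

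A second near-fixed protein change lay close to the first in 3 pools. RRC5 carried G81D in RRS1 (YOR294W), an essential gene of ribosome assembly, on 100% of 60 reads, 959 bases from the UAF30 frameshift. RRS1 and UAF30 are neighbouring protein-coding genes in the R64 annotation. RRC1 carried V451I in NGL2 (YMR285C), an RNA endonuclease gene, on 96% of 64 reads, 34.8 kb from the RRN9 change. RRC4 carried E290K in ECM32 (YER176W), a helicase gene, on 90% of 52 reads, 33.0 kb from the CHD1 change. These 12 calls in 8 pools were the near-fixed protein changes with a call score of 200 or more, no parental call at the position and at most 1 other list with a call there, a restriction chosen after the data were examined.

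**Figure D1:**
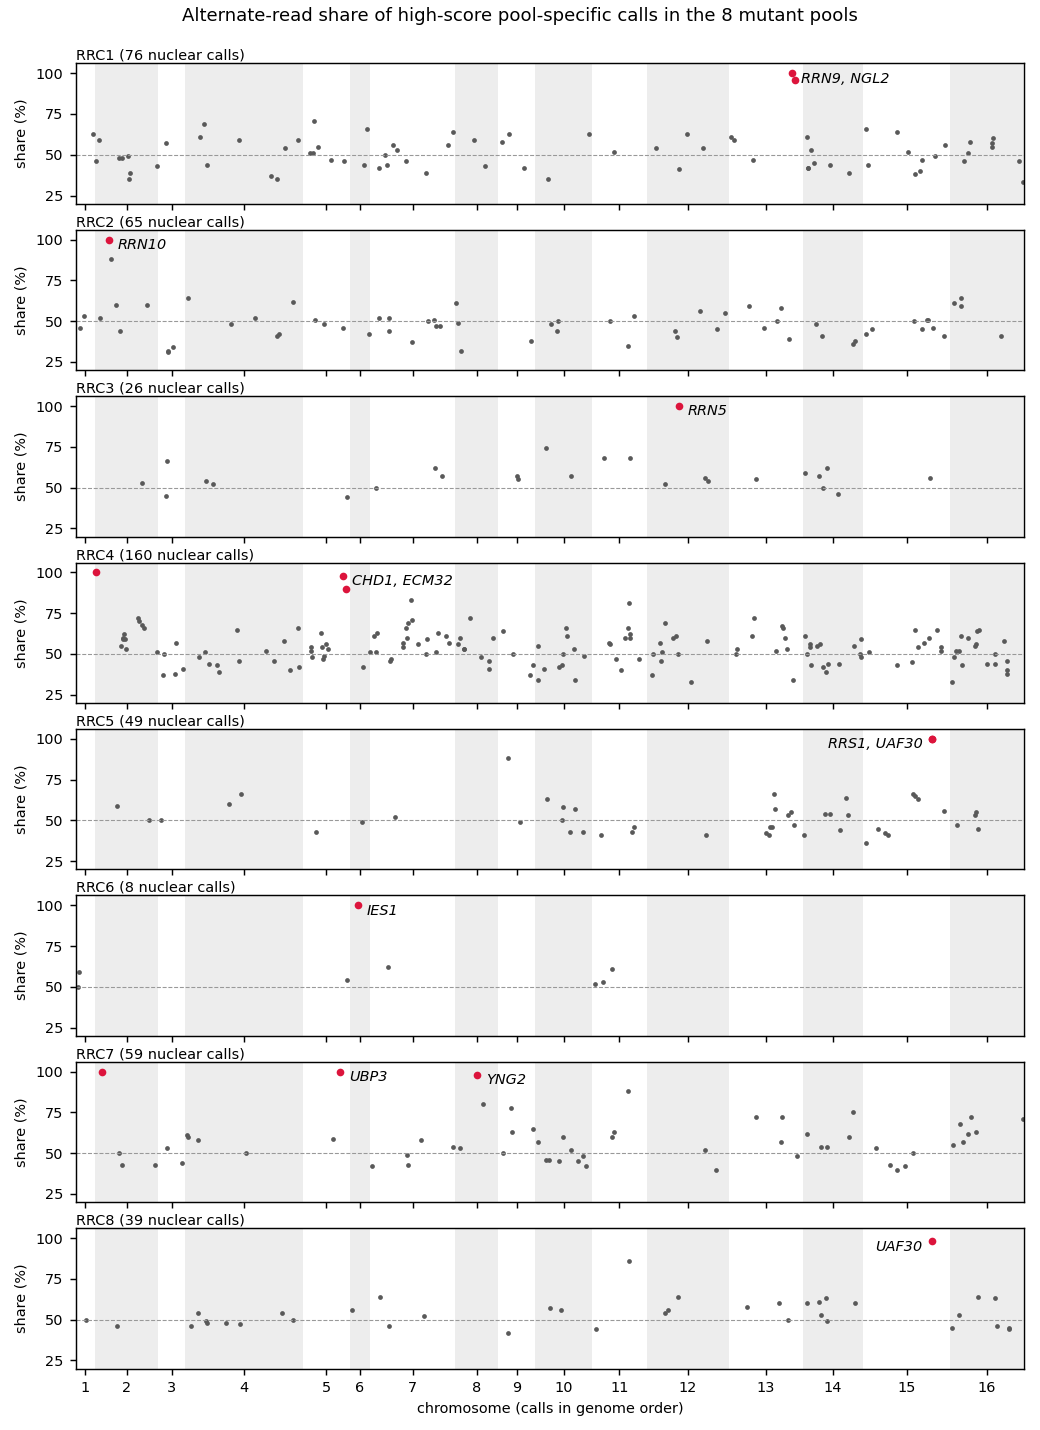
Alternate-read share in percent (vertical axes) against position along the 16 nuclear chromosomes (horizontal axis) for pool-specific calls with a score of 200 or more, no parental call at the position and at most 1 other list with a call there. Each panel is 1 mutant pool, with near-fixed calls in red (named where they change a protein, at 90 to 100%), other calls in grey and a dashed line at 50%.

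Without that restriction, ALT2, ASG1, COS5, YHL041W, FLO9 and YCR024C-B had near-fixed protein changes in 4 to 8 pools each. The 8 pools held 1350 calls absent from the parental list at a depth of at least 10 reads, from 119 in RRC8 to 262 in RRC4. Of these, 200 were near-fixed (share of at least 90% and adjusted p under 0.05), 17 in RRC2 to 35 in RRC5, and 58 of them changed a protein. A dinucleotide deletion giving a frameshift in ALT2 (YDR111C) was near-fixed in all 8 pools. An inserted codon in ASG1 (YIL130W), D888ND, was near-fixed in 7 pools, P50R in the subtelomeric gene COS5 (YJR161C) in 6, a homopolymer frameshift in YHL041W in 6, R313K in the flocculin gene FLO9 (YAL063C) in 4, and a homopolymer frameshift in YCR024C-B in 4. YAL004W, YBL100W-A and YBL100W-B followed with 2 pools each. MTM1, NUM1, YLR410W-B, YMR045C, YMR046C, YDR210C-D and YBL005W-A each had a near-fixed protein change in 1 pool, at positions where the parental list held another allele. Of the 200 near-fixed calls, 148 were also in the list of another mutant, and 152 had a parental call of another allele at the position.

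Of the 7 gene lists fixed beforehand, the UAF list was the only one with near-fixed protein changes, in RRN5, RRN9, RRN10 and UAF30 of its 8 genes. These are the same genes that the pool titles name, so the result for this list is not independent of the titles. Only the UAF30 frameshift in RRC8 was found in a pool without a gene in its title. The other 6 lists held 10 protein-changing pool-specific calls below 90%. Among the core factor and TBP genes, RRN3, an RNA polymerase I initiation factor gene, had S354N in RRC2 on 50% of 86 reads. Among the 14 RNA polymerase I subunit genes, RPA135 had V685I in RRC8 on 63% of 72 reads and RPC40 had A286T in RRC4 on 38% of 67 reads. Among the 17 silencing genes, RFM1 had R268K in RRC3 on 56% of 64 reads. RAD52, the recombination gene, had P432L in RRC8 on 58% of 53 reads, and RPD3, a histone deacetylase gene, had S101N in RRC5 on 41% of 89 reads. TOR2 had A1304T in RRC7 on 36% of 80 reads. In the remodelling and mediator list, STH1 had A1329T in RRC1 on 63% of 61 reads, SRB2 had S53F in RRC4 on 72% of 76 reads, and CYC8 had H537Q in RRC4 on 21% of 14 reads, the last with a call score of only 6.98. SIR2, NET1 and FOB1 had no pool-specific call at this depth within the gene. CTR9 carried W927R and G926E in all 9 lists, the parental one included, at 97 to 100% of reads.

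Calls close to the named gene were few, and over all pool-specific calls the difference from the rest of the genome did not pass the test at RRN9, RRN10, RRN5 or UAF30. Near RRN9 in RRC1, 2 calls within 50 kb averaged 63% against 49.0 ± 25.4% (SD) for 158 others (exact permutation test over calls, p = 0.470). Near RRN10 in RRC2, 2 calls averaged 57% against 43.4 ± 24.8% for 160 others (exact permutation p = 0.468). Near RRN5 in RRC3, 1 call stood at 26% against 43.7% (exact permutation p = 0.506). Near UAF30 in RRC5, the RRS1 call at 100% stood against 50.6% for 162 others (exact permutation p = 0.135). All tests were two-sided, all 4 adjusted p were 0.506, and neighbouring calls are not independent replicates. The call near RRN5 had a score of only 4.13 on 15 reads. The lower call near RRN9 (30% of 13 reads, score 12.3) and that near RRN10 (26% of 30 reads, score 6.98) were each in 2 mutant lists. With such low-score calls these averages say little for or against linkage. The window moved the differences, to -19.3 percentage points for the 1 call within 25 kb of RRN9, the low-score one (exact permutation p = 0.475). Near RRN10 the difference was 28.3 for the 3 calls within 100 kb (exact permutation p = 0.0425, adjusted p = 0.170). Restricted, after the data were examined, to G:C to A:T calls with a score of 200 or more, 1 call lay within 50 kb in each of RRC1, RRC2 and RRC5. NGL2 at 96% stood against 52.0% near RRN9, the call downstream of RRN6 at 88% against 46.6% near RRN10, and RRS1 at 100% against 51.1% near UAF30. The exact permutation p values were 0.0267, 0.0167 and 0.0217, each with adjusted p = 0.0267, and those at RRN10 and UAF30 were the smallest that a single call allows. In RRC1 a synonymous call in FLO9 on chromosome 1 (position 25506, 100% of 24 reads) was higher than NGL2, at a position called in all 9 lists. RRN5 had no such neighbour.

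Among the high-score G:C to A:T calls with no parental call at the position and at most 1 other list with a call there, shares were highest close to the near-fixed genes. No test was made over distance, and CHD1, UBP3 and YNG2 were added after their values were seen. Of the 4 calls within 50 kb of such a gene, NGL2, ECM32 and RRS1 were themselves near-fixed protein changes. Only the call downstream of RRN6 (88%) was not, so the average within 50 kb is not independent of the choice of near-fixed genes. Over RRN9, RRN10, RRN5, CHD1, UAF30, UBP3 and YNG2 together, the 4 calls within 50 kb averaged 93.5 ± 5.51% (SD over calls), the 8 calls from 50 to 200 kb 58.3 ± 10.6% and the 22 calls farther away on the same chromosome 52.8 ± 7.91%. The 418 calls on other chromosomes averaged 52.2 ± 9.17% (highest 83%). The highest lay downstream of NMA2 on chromosome 7 in RRC4, where no call of this set was near-fixed. Near it were YGR021W at 71%, LEU1 at 69% and PGD1 at 66%, while PEF1 stood at 56%, and this group was not tested. The 418 include LEU2 calls in RRC3 (66% of 512 reads) and RRC7 (53% of 384 reads) and the mitochondrial call of RRC2 (37% of 1218 reads). With the 4 calls that these filters left out, at FLO9 and at position 91965 of LEU2, the 422 calls averaged 52.4 ± 9.74% (highest 100%). IES1 in RRC6 and UAF30 in RRC8 had no such call on their chromosome. ECM14 in RRC7, 85.8 kb from YNG2, had a share of 80% on 56 reads. MAM1, 97.7 kb from UBP3 in the same pool, had a share of 59% on 57 reads.

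**Figure D2:**
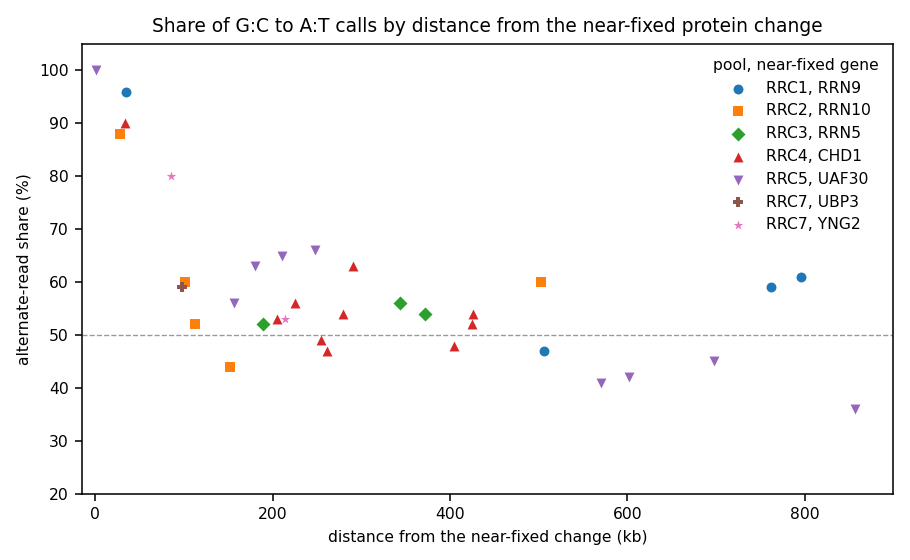
Alternate-read share in percent (vertical axis) of pool-specific G:C to A:T calls with a score of 200 or more, no parental call at the position and at most 1 other list with a call there, against distance in kb (horizontal axis) from the near-fixed protein change on the same chromosome. Each symbol is 1 call, coloured by pool and gene, the dashed line marks 50%, and the 4 calls within 50 kb lie at 88 to 100%.

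Single-base calls absent from the parental list were mostly G:C to A:T transitions, the class of the RRN9, RRN10, RRN5, CHD1, UBP3 and YNG2 changes. They made up 687 of 1076 pool-specific single-base calls (63.8%), against 468 of 1592 calls shared with the parental list (29.4%). RRC4 had the highest share, 181 of 222 (81.5%, exact 95% interval 75.8 to 86.4%), and RRC3 a lower one, 81 of 157 (51.6%, 43.5 to 59.6%). The share was higher among pool-specific calls in 7 pools by Fisher's exact test over calls, with adjusted p from 1.46e-28 in RRC4 to 3.30e-05 in RRC3. RRC6, whose near-fixed change in IES1 is a 1-base deletion, did not pass, with 41 of 133 calls (30.8%) against 45 of 156 (28.8%, Fisher's exact test, adjusted p = 0.796). With a minimum depth of 20 reads RRC6 passed as well, at 45.3% (Fisher's exact test, adjusted p = 0.00263), and so it did with a score of at least 200, a setting chosen after the data were examined, at 7 of 7 calls (100%, Fisher's exact test, adjusted p = 0.000147). It did not pass among calls absent from every other pool with a share from 0.2 to 1, at 33.3% (Fisher's exact test, adjusted p = 0.498). In the restricted set, the number of G:C to A:T calls ranged from 7 in RRC6 to 155 in RRC4.

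**Figure D3:**
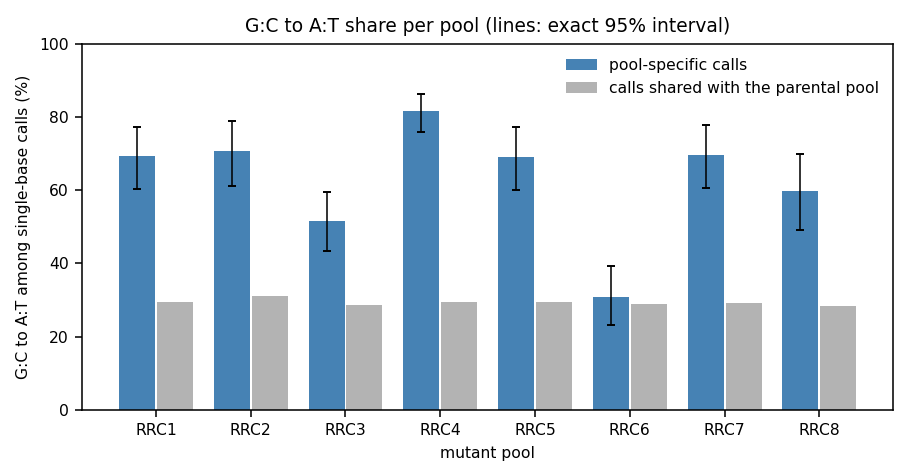
Percent of single-base calls that were G:C to A:T transitions (vertical axis) in each mutant pool (horizontal axis), among pool-specific calls (blue) and calls shared with the parental pool (grey). Lines on the blue bars are exact 95% binomial intervals over calls, and RRC6 has its blue bar at 30.8% and its grey bar at 28.8%.

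Pairs of mutant pools shared few pool-specific calls. The 28 pairs shared 17.96 calls on average (9 to 31), with a Jaccard index of 0.0293 to 0.0885. The 16 pairs from the same starting strain shared 16.3 calls on average and the 12 pairs from different strains 20.2, with no test made. RRC5 and RRC8 shared 23 calls, the UAF30 frameshift among them. Their Jaccard index of 0.0885 was the highest of the 28 pairs, and 3 of these calls were found only in this pair. Of the G:C to A:T calls with a score of 200 or more, 2 of the 28 pairs shared 1 each, RRC1 with RRC4 and RRC1 with RRC8, and RRC5 and RRC8 shared 0. RRC1 and RRC4 shared a call in LEU2, at position 91965, which was called in 5 lists. RRC1 and RRC8 shared a call in FLO9, at position 25506, which was called in all 9 lists, the parental one included.

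Protein-changing pool-specific calls at different positions in at least 2 mutant pools fell in 24 genes. The most positions were 8 in YMR317W and 5 in YBL113C, both open reading frames without a standard name, followed by 4 each in DAN4, FLO9 and ASG1. YEL077C, YHL050C and YIL169C had 3 each. Call scores were at most 72 in YMR317W and at most 97 in DAN4. With the restriction on score, parental call and other lists, YBL113C kept 1 position and ASG1 kept 2. YMR317W, DAN4, FLO9, YEL077C, YHL050C and YIL169C kept 0. The number of positions in these 8 genes therefore says little on repeated hits. The other 16 genes, with 2 positions each, were ALK1, AST1, ECM32, EST2, FAS2, FIT1, GAL10, IRC23, MBR1, MCD4, NUM1, TRS120, YAL004W, YFR016C, YJL045W and YLR296W. Apart from ECM32 in RRC4, NUM1 and YAL004W, none of these 16 exceeded 63% of reads. FAS2, a fatty acid synthase gene, carried E4K in RRC8 on 53% of 65 reads and P1029S in RRC4 on 52% of 61 reads. GAL10, of galactose use, carried P593S in RRC5 on 59% of 79 reads and G75D in RRC8 on 46% of 90 reads.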

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

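The comparisons with the parental pool below were chosen after the read depths were seen, and so was the test of the LEU2 explanation.

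Signals outside the variant comparisons stood out in the read depth of the mitochondrial genome and of LEU2, the gene of a leucine biosynthesis enzyme that serves as a selectable marker. At the 3 mitochondrial positions called in every list, including COX1, the median reads in the parental pool were 17.7 times the library's median depth at calls with a score of 200 or more, 60.5 reads (bootstrap 95% interval 16.5 to 19). The interval lay wholly above the parental one in 7 mutant pools, which compares single libraries and not strains, since it covers counting within 1 library only. The ratio was 20.5 in RRC1, 31.6 in RRC3, 25.1 in RRC4, 22.1 in RRC5, 23.1 in RRC6, 39.0 in RRC7 and 24.7 in RRC8, and in RRC2, whose interval overlapped the parental one, 19.4. With the median depth of all calls as the divisor, an alternative added after the data were examined, the parental ratio was 28.9 and RRC1 (27.9) and RRC2 (26.7) lay below it, while the other 6 pools lay above it at 30.7 to 72.5. RRC2 alone had a mitochondrial call absent from the parental list, at position 52357 on 37% of 1218 reads. RRC3 alone lacked the call at position 39517 in COB, which stood at 99% of reads in the parental pool. The ratio also varied between the 3 positions, from 29.1 to 40.7 in RRC3 and from 22.0 to 36.6 in RRC6. These medians therefore need not hold for the whole mitochondrial genome, and the cause was not tested.

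At position 91728 of LEU2 (YCL018W, chromosome 3) the parental pool had 1272 reads, 21.0 times the same median depth (19.7 to 22.5), with a synonymous change at V135 on 81% of them. RRC6 lay above the parental pool at 25.3 times (23.6 to 29.2), 6 pools lay below it, down to 5.20 times in RRC1, and the interval of RRC8 (22.9 times) overlapped the parental one. At position 92106, also called in every list, RRC6 stood at 16.9 times and the parental pool at 17.3. With the median depth of all calls as the divisor, position 91728 gave 58.5 in RRC6, 34.4 in the parental pool and 33.5 in RRC3. Whether RRC6 and RRC3 stand apart from the parental pool therefore depends on the position or the divisor. RRC1 and RRC4, the 2 pools from YTT67, had the lowest ratios in each of these settings. Their ratios were 5.20 and 7.42 at 91728, 5.59 and 7.10 at 92106, and 7.09 and 9.10 with the other divisor. A link with the starting strain was not tested. A changing proportion of 2 LEU2 sequences may account for part of the differences in LEU2 depth and stays open. The share at 91728 ranged over 58 percentage points across the 9 libraries. The 3 positions called in every list differed by 2 to 6 points within 8 libraries but by 11 in RRC3 (78% at 91728 and 67% at 92106). Reads with the reference base at 91728 were 3.21 to 4.40 times the median depth and those with the other base 1.36 to 21.0 times. At 91965, called in RRC1, RRC2, RRC4, RRC5 and RRC7, reads with the other base varied little, at 3.25 to 3.70 times. At 91575, called in RRC1, RRC4 and RRC7, they stood at 3.77 to 3.82 times. A steady LEU2 sequence beside another of changing amount would give such values, but the difference within RRC3 was not accounted for. Lists without a call there give no depth, and no biological explanation was tested.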

How the results depend on the processing

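No paired analysis was possible because each sequenced pool is a single library and the samples that share replicate numbers in the labels were not analysed here. Lists give depth only at called positions, which limits every statement on absence, and RRC6 has the lowest depth. Of 290 alternative values, 161 were classed as unchanged, 123 as moved, 5 as stronger and 1 as reversed. For counts, unchanged means within 1.5 times the main value. For the title genes the 1 alternative, a share of at least 90%, could not change anything, since all 4 calls stand at 100%. RRN10 and RRN5 had no call within 25 kb and gave no value there. Tests with the score of at least 200 or with matching by position alone were chosen after the data were examined. Counts run from RRC1 to RRC8, with the sum in front.

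Pool-specific calls numbered 2261 with the shortened lists, by construction since these kept parental calls (295, 301, 280, 273, 237, 257 and 233 without RRC4, which stayed within 1.5 times), and 483 (76, 66, 26, 160, 49, 8, 59, 39) with the score restriction. Absence from the other 7 lists left 104 in RRC1 and 71 in RRC8, and a depth of 20 left 86 in RRC6.

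Near-fixed calls fell to 52 (3, 7, 5, 7, 11, 6, 7, 6) when absent from the other 7 lists, to 46 (7, 2, 7, 10, 6, 4, 5, 5) with single-base calls only, to 48 (5, 3, 7, 7, 6, 7, 7, 6) with no parental call at the position, to 14 (2, 1, 1, 3, 2, 1, 3, 1) with the score restriction, and to 130 at a depth of 20 (12 in RRC3, 21 in RRC5, 9 in RRC6, 16 in RRC7). With the shortened lists they rose to 596 (81, 79, 73, 77, 80, 64, 70, 72).

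Near-fixed protein changes fell to 17 (2, 1, 2, 2, 4, 4, 2, 0), 18 (4, 1, 3, 4, 2, 1, 2, 1), 19 (3, 2, 2, 3, 2, 2, 3, 2) and 12 (2, 1, 1, 2, 2, 1, 2, 1) under these settings in the same order, rose to 181 (26, 28, 22, 23, 21, 21, 21, 19) with the shortened lists, and were 5 in RRC5 and 5 in RRC6 at a depth of 20. The 12 calls of RRN9, NGL2, RRN10, RRN5, CHD1, ECM32, RRS1, UAF30 (RRC5 and RRC8), IES1, UBP3 and YNG2 have 34 to 77 reads and were all kept at a depth of 20. No minimum depth, matching by position, 80%, no test and the shortened lists, which lack parental calls only, could drop none of them by construction. Of them 11 were kept at 95%, 10 when absent from the other 7 lists (UAF30 is in 2) and 9 with single-base calls only (the 3 frameshifts drop out).

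The G:C to A:T share over all pools rose from 63.8% to 75.8% for calls absent from every other pool with a share from 0.2 to 1, to 73.8% at a depth of 20 and to 96.5% at a score of at least 200. RRC6 did not pass under the first of these (33.3%, Fisher's exact test, adjusted p = 0.498) and passed under the others, at 45.3% (depth of 20) and 100% (score); the cause was not tested. Near RRN9 the difference turned from 14 to -19.3 percentage points within 25 kb (exact permutation p = 0.475), where 1 call with a score of 12.3 was left. Near RRN10 the difference rose from 13.6 to 28.3 within 100 kb (3 calls, exact permutation p = 0.0425, adjusted p = 0.170). With high-score G:C to A:T calls the difference was 44.0 near RRN9, 41.4 near RRN10 and 48.9 near UAF30. These 3 values passed the threshold, but each came from 1 near call whose share had been seen. At RRN10 and UAF30 the p was the smallest possible. Calls shared per pair fell from 17.96 to 3.71 at a score of at least 200 (3.56 in pairs of the same starting strain, 3.92 in others). The cause of these changes was not tested beyond what the settings remove.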

Other observations

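The tests below were chosen after the shared frameshift and the pair of changes in RRC7 were seen; the prediction on calls near YNG2 was set before its value was known, but the calls it is compared with were redefined after a first value had been seen.

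Over all genes, those of the fixed lists included, 238 high-score pool-specific protein changes were found in a single list each, and 7 genes carried them in more than 1 pool: ALK1, ASG1, FAS2, GAL10, IRC23, MBR1 and YJL045W. ASG1 counts here through the inserted codon N887IN in RRC5, at position 105438. It lies within 5 bases of the D888ND insertion at 105433, called in 7 other pools, so it may not be a separate hit. Random placement of the same number of calls on 6002 protein-coding genes of R64 by gene length gave a median of 6 such genes (95% of draws between 2 and 10), and 33.4% of 10000 draws gave as many.

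RRC5 and RRC8 carried the same UAF30 frameshift at 100% and 98% of reads. Reads carried over from the RRC5 library are argued against, since the 37 high-score G:C to A:T calls found only in RRC8 had a median share of 53%, and RRC5 reads making up nearly all of that library would leave them near 0. A single mutant clone behind both pools is argued against as well, since 0 of the 46 such calls of RRC5 were in the RRC8 list (upper exact 95% bound 7.71%), RRS1 G81D included. An allele already present in part of the starting culture, or a repeat hit of the same G run, may both account for the pattern and cannot be told apart. The parental list had no UAF30 call, but its 363 calls with 10 or more reads go no lower than a share of 11% (41% among those with a score of 200 or more), so a rarer allele may have gone without a call.

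In RRC7, UBP3 E751K and YNG2 C225Y were both near-fixed although they lie on different chromosomes, and so was a call downstream of RPS8A on chromosome 2 (100% of 53 reads). Fixation by chance in a pool of few clones stays open. The spread of 45 high-score G:C to A:T calls outside chromosomes 2, 5 and 8 gave an effective 39.4 clones (bootstrap 95% interval 26.02 to 84.6). That of 48 calls with chromosome 2 kept gave 38.8 (25.9 to 81.9). The score filter narrows the spread and so raises the number, and leaving out chromosomes with near-fixed changes can do the same. How far was not measured, so the estimate cannot decide on few clones. A call error at the YNG2 site is argued against by 1 neighbouring call only, since the share in ECM14 (80%) was 24.04 percentage points above the mean of those 45 calls (56.0 ± 9.88%, the highest at 78%; exact permutation p = 0.0217, the smallest that 1 call against 45 allows). The first set of 30 calls gave 24.5 points (exact permutation p = 0.0323), and 13 calls on chromosomes without any near-fixed call gave 24 points (exact permutation p = 0.0714, and all 3 p are the smallest possible). Whether both changes were selected was not tested.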
